A study of Homo sapiens with 12 samples.

How the data were processed

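RNA from HEK293 cells was sequenced as 12 poly-A selected libraries, in 4 groups of 3: wild type or EXT1 knockdown cells, each in adherent or suspension culture. Groups were taken from the sample titles, which also number the replicates. Cells had gone through 5 passages before collection. Adherent cells grew in flasks in DMEM with serum and were trypsinized at collection, whereas suspension cells grew in serum-free EX-CELL 293 medium shaken at 120 rpm, both at 37 °C and 5% CO2. The culture comparison therefore differs in medium, serum, shaking and harvest at once. The labels do not say how EXT1 was knocked down, whether the knockdown cells were a clone or a pool, or whether the replicates of a group came from separate cultures. P-values thus measure only the spread between these libraries, which may be technical.

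The deposited count table holds whole-number reads per gene, which the authors produced with HISAT2 (version not given in the sources used here) and featureCounts 1.5.0 on GRCh38, per the submitters' processing notes. The deposited FPKM table holds the same reads per kilobase of gene length and library size; in each library every FPKM equals the value computed from the count table times 1 constant between 0.942 and 1.029. The annotation release and the strand setting of the counting are not given in the sources used here. The labels' protocol describes both a directional and a non-directional way of making the second strand, so reads of overlapping and antisense genes cannot be told apart. Reads shared with near-identical copies leave SULT1A1, the IFITM genes, HSPA1A and HSPA1B, the clustered protocadherins and ribosomal protein genes with pseudogenes uncertain. Coordinates are those of the deposited tables on GRCh38.

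The tables list 58735 genes, of which 36513 had at least 1 read. Library totals ran from 13.9 to 21.4 M reads assigned to genes. No row lacked a gene ID and no column went unused. No 2 libraries of a group were duplicates: the chi-square per degree of freedom between replicate counts ran from 2.63 to 26.8, with the 3 highest values all among the wild-type adherent libraries.

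Raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered by group with filterByExpr, which left 17115 genes holding 99.9% of the reads. Libraries were scaled by TMM, 1 model with a mean per group was fitted to all 12 libraries, and 5 contrasts were tested with the quasi-likelihood F-test: knockdown against wild type in each culture, suspension against adherent in each line, and the difference between the 2 knockdown effects, called the interaction. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. All adjusted p-values of single genes come from this edgeR test. Log2 fold changes carry edgeR's prior count, which pulls changes of genes with very few reads toward 0, and standard errors (SE) are the absolute log2 fold change divided by the square root of F. CPM values are library-scaled counts (TMM), given as mean ± SD over the 3 libraries of a group. Counting intervals are exact binomial intervals at 95% on summed reads, given for named genes with under 10 reads in a library of 2 groups compared. They cover counting error only, since PCR copies are not separate molecules, and interaction values carry none.

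Gene lists were tested with camera (limma 3.58.1) on voom values of the same libraries, with the preset correlation of 0.01, adjusted over the 39 lists with at least 5 measured members. Of 41 lists, the leukocyte and hepatocyte markers had too few measured members to test. The lists name 1096 symbols, of which 1056 were matched to an ID and 3 were not; the others were second names for a gene already in the same list. Camera was repeated with a correlation estimated from the residuals, and fry was run as a test that does not compare a list with other genes. The genes of each of 23 chromosomes were tested in the same way, and medians per chromosome were taken over the 11689 genes with a mean CPM of at least 5.

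The lists, the contrasts, the alternatives other than 1, and the rule for naming genes were fixed before the data were examined. Of the later tests of explanations, 7 were chosen after the results were seen, which is said where they are given. The rule named EXT1; the 10 largest rises and falls per comparison of 2 groups among protein-coding genes past the threshold, with a mean CPM of at least 5 and groups that did not overlap; the 5 largest of each sign for the interaction and for genes changed alike in both comparisons of a kind; and up to 4 members of a list with the largest change, plus the best-known member where it did not change. A few genes named outside this rule were chosen after their values were seen, which is said beside them.

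The fit was tested on simulated counts of 17115 genes, made from the gene means, spread and library sizes of all 12 libraries. Changes were placed in the adherent knockdown libraries alone. EdgeR recovered 71% of genes changed by a log2 fold of 1 and 92% of those changed by 2, and 5.78% of its calls were false. A list shifted by -0.5 and a chromosome shifted by 0.3 were both recovered by camera with 0 other sets called. The simulated genes were drawn independently. The simulation therefore cannot show how often camera calls sets falsely where genes are correlated.

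Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), size factors or library size in place of TMM, no filter and a stricter filter, only the 6 libraries compared, the replicate number as a block, and each library left out in turn. A fit with chromosome medians removed was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.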

Results

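Messenger RNA was measured in HEK293 cells, a human embryonic kidney line widely used to make proteins and viral vectors, in a series on modified HEK293 cells meant for higher output of biologics such as adeno-associated virus (AAV) vectors. The cells were wild type or carried a knockdown of EXT1, a glycosyltransferase that with EXT2 polymerizes the chains of heparan sulfate. Each line was grown attached to flasks or in shaken suspension, which gave 4 groups of 3 libraries. Reads assigned to genes averaged 18.9 ± 2.27 M reads per library in wild-type adherent cells (SD, n = 3), 16.4 ± 2.15 M in adherent knockdown cells, 16.4 ± 1.77 M in wild-type suspension cells and 15.8 ± 1.52 M in suspension knockdown cells.

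EXT1 (ENSG00000182197) lies on the minus strand of chromosome 8 from 117794490 to 118111853 (GRCh38). Its level was 53.2, 53.1 and 51.8 CPM in the 3 wild-type adherent libraries and between 11.9 and 12.5 CPM in the 3 adherent knockdown libraries. In suspension it was 49.5, 54.6 and 47.9 CPM in wild type and 15.4, 13.1 and 15.3 CPM in the knockdown. EXT1 was thus 4.34-fold lower in knockdown cells in adherent culture (log2 fold change -2.12, SE 0.09, adjusted p = 5.67e-12 in edgeR's quasi-likelihood test) and 3.48-fold lower in suspension (log2 fold change -1.80, SE 0.09, adjusted p = 4.77e-11). Wild-type cells did not differ between cultures past the threshold (-0.06, adjusted p = 0.571). In knockdown cells EXT1 was slightly higher in suspension (0.27, SE 0.10, adjusted p = 0.0246), a call lost with limma-voom (adjusted p = 0.0541), without a filter on low counts (adjusted p = 0.0621), with limma-trend on log2(FPKM + 1) (adjusted p = 0.0530) and without EXT1kd suspension replicate 3 (adjusted p = 0.0634). The difference between the 2 knockdown effects on EXT1 was 0.32 (SE 0.12, adjusted p = 0.0677), and it passed with the stricter filter (adjusted p = 0.0372), without EXT1kd suspension replicate 2 (adjusted p = 0.0375) and with chromosome medians removed (adjusted p = 0.0114).

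**Figure D1:**
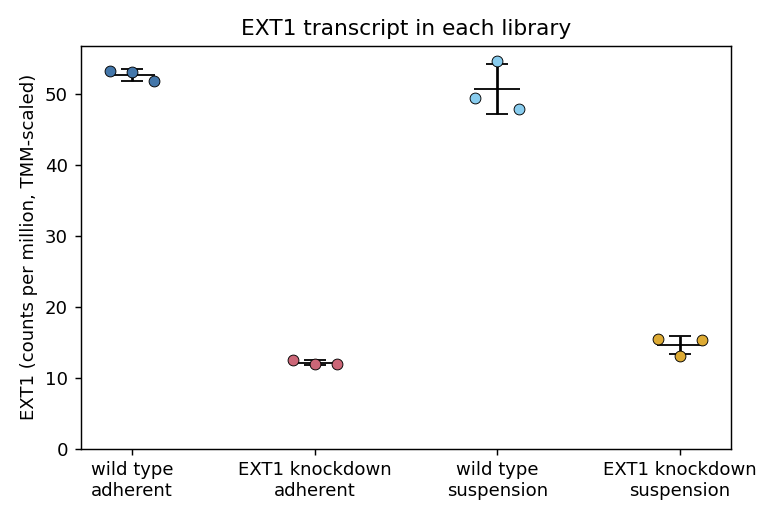
EXT1 level in CPM (counts scaled by TMM) in each library of the 4 groups, with points for libraries and bars for mean ± SD (n = 3). All 6 knockdown libraries lie between 11.9 and 15.4 CPM, below all 6 wild-type libraries at 47.9 to 54.6 CPM.

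Culture separated the libraries most. The first principal component of log2 CPM held 55.6% of the variance and parted adherent from suspension libraries. The next held 11.7% and set wild-type adherent together with suspension knockdown libraries against the other 2 groups. The component after it held 9.95% and parted the lines in the same direction in both cultures, with all 6 wild-type libraries below 0 and all 6 knockdown libraries above. The share of reads from mitochondrially encoded protein genes was 5.21 ± 0.46% in wild-type adherent, 4.69 ± 0.25% in adherent knockdown, 6.38 ± 0.87% in wild-type suspension and 6.51 ± 1.01% in suspension knockdown libraries (SD, n = 3). In exact two-sided permutation tests of the 4 pairs of groups, p was 0.2 for knockdown in adherent culture, 1 for knockdown in suspension, 0.2 for culture in wild type and 0.1 for culture in knockdown cells, where 0.1 is the smallest p that 3 against 3 libraries allow.

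**Figure D2:**
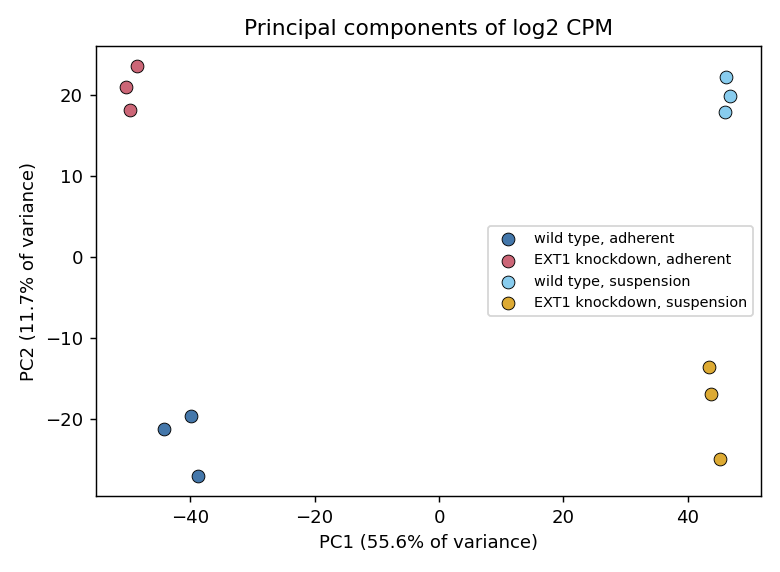
First and second principal components of log2 CPM, with 1 point per library coloured by group and the percent of variance on each axis. The first component (55.6%) parts the cultures, and the second (11.7%) separates the lines in opposite directions in the 2 cultures.

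The first comparison asked what lower EXT1 went with in adherent cells. Most listed targets and feedback inhibitors of fibroblast growth factor (FGF) and ERK signalling fell. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, fell to 1.40 ± 0.42 CPM, 7.11-fold below wild type (SD, n = 3; log2 fold change -2.83, SE 0.17), and the ETS transcription factors ETV5 (-2.47, SE 0.10), ETV4 (-2.20, SE 0.11) and ETV1 (-1.84, SE 0.12) fell with it. Of the 19 measured members of this list 0 rose, 14 fell and 5 did not pass, with 15 lower when adjusted over the list alone. The list's median change was -0.56 and its camera call (adjusted p = 7.89e-12) was the only list call of this comparison to hold with an estimated correlation (adjusted p = 0.0137). CCND1 and MYC, the list's cell-cycle members, were named after their values were seen. They were at -0.08 and -0.10 and did not pass (adjusted p = 0.381 and 0.334). The feedback inhibitors SPRY1, SPRY2 and DUSP5, also looked up afterwards, overlapped between wild-type and knockdown libraries. SPRY1 was at 19.1 to 22.6 CPM in wild type and 18.4 to 22.5 CPM in the knockdown. SPRY2 was at 19.9 to 25.1 and 19.4 to 21.1 CPM.

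**Figure D3:**
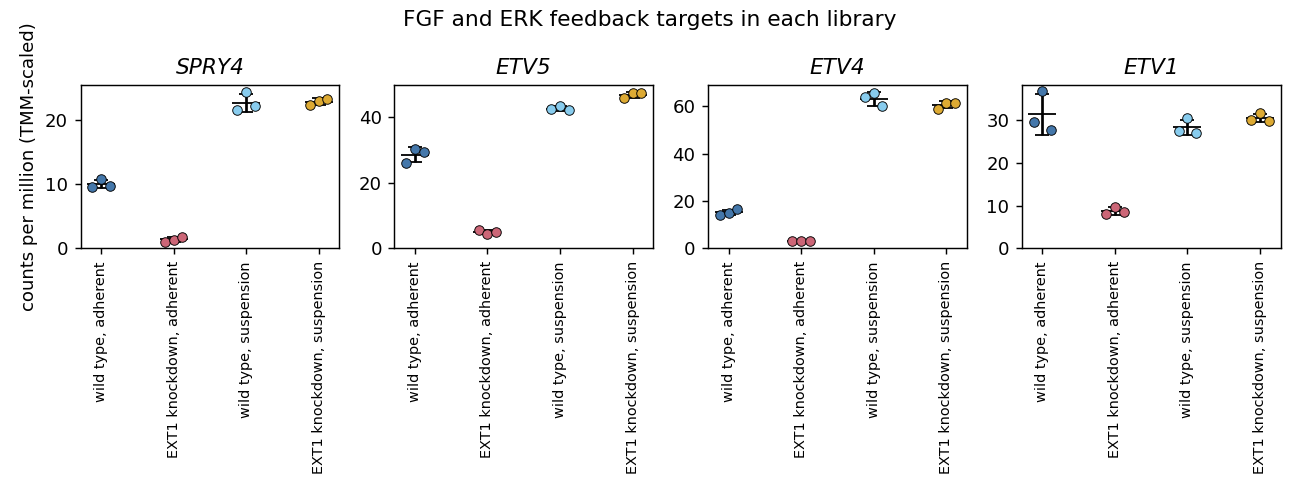
Levels of SPRY4, ETV5, ETV4 and ETV1 in CPM in each library, with points for libraries and bars for mean ± SD (n = 3 per group). All 4 genes are lowest in the adherent knockdown libraries, and in suspension the knockdown effect was between -0.06 and 0.13 on the log2 scale with none past the threshold.

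The largest rise in adherent knockdown cells was that of FUT9, a fucosyltransferase that makes the Lewis X epitope, from 1.94 ± 0.31 to 14.5 ± 0.50 CPM (SD, n = 3; 2.91, SE 0.19). The LIM protein CSRP1 rose by 2.88 (SE 0.13) and the actin cross-linker FLNC by 2.75 (SE 0.10). SERPINB9, an inhibitor of granzyme B (2.40), the small proteoglycan LUM (2.37), the matrix glycoprotein EMILIN2 (2.06), FRRS1L (2.05), RGS3 (1.95), PARP14 (1.92) and RIN3 (1.83) completed the 10 largest rises. The other large falls were the inositol phosphatase INPP5D (-2.46), MID1IP1, a regulator of lipid synthesis (-2.45), the semaphorin co-receptor PLXNA4 (-2.35), the sulfotransferase SULT1A1 (-2.20) and the cadherin CDH11 (-1.96). SULT1A1 has near-identical paralogs, PLXNA4, 5.19-fold lower on 22 knockdown reads (95% exact binomial interval 3.28 to 8.56), lost its call on the log2(FPKM + 1) scale (adjusted p = 0.0587), and INPP5D rested on 18 reads in the 3 knockdown libraries, for a 5.60-fold lower level (interval 3.39 to 9.79).

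Heparan sulfate enzymes went both ways. Of 19 measured members of the polymerization and modification list other than EXT1, 5 rose and 5 fell, with no list call (adjusted p = 0.999). The sulfatase SULF2, which trims sulfate from finished chains, fell by 0.81 on the log2 scale (SE 0.08), while heparanase HPSE rose by 0.81 (SE 0.16), the related transferase EXTL3 by 0.52 (SE 0.07) and EXT2 by 0.51 (SE 0.07). HPSE, EXTL3 and EXT2 lie on chromosomes 4, 8 and 11, whose genes had medians of 0.24, 0.16 and 0.29 in this comparison. Their rises thus may include these shifts. Of 15 heparan sulfate proteoglycan core proteins 1 rose and 2 fell (adjusted p = 0.691). XYLT1, which starts the linker to the core protein, fell by 1.82 (SE 0.13).

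Another 4 lists had more members higher than lower under the preset correlation. Members named below on raised chromosomes carry that shift too, such as FJX1 and VPS51 on chromosome 11 (median 0.29). YAP and TAZ targets had 13 of 24 members higher and 1 lower (15 and 1 when adjusted over the list alone, adjusted p = 0.00199), with MYOF at 1.04 and FJX1 at 0.72, and adjusted p = 0.0614 with an estimated correlation. Factors for AAV attachment and entry had 12 of 30 higher and 1 lower (13 and 2 when adjusted over the list alone, adjusted p = 0.00199), led by VPS51 (0.61) and the integrin subunit ITGAV (0.48), and adjusted p = 0.118 with an estimated correlation. Extracellular matrix genes had 15 of 31 higher and 5 lower (the same counts when adjusted over the list alone, adjusted p = 0.00346, and adjusted p = 0.403 with an estimated correlation). LAMA1 (1.53) and the lysyl oxidase LOXL2 (1.17) rose, whereas fibrillin FBN1 fell (-1.38). Integrins and focal adhesion had 14 of 32 higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.00762, and adjusted p = 0.0827 with an estimated correlation), with ITGA3 at 0.77 and ITGA8 against the list at -0.92.

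Cytosolic ribosomal proteins had 2 of 50 members higher and 22 lower (2 and 23 when adjusted over the list alone), with RPS23 at -0.63 and RPS27 at -0.69. The call (adjusted p = 1.16e-05) was lost at adjusted p = 0.517 with an estimated correlation. RPS27 rested on WT adherent replicate 3, without which its change was -0.21 (adjusted p = 0.0900), and it also lost its call with DESeq2 (adjusted p = 0.0747), on both FPKM scales (adjusted p = 0.0973 and 0.0919) and without EXT1kd adherent replicate 2 (adjusted p = 0.0523). ATF4 targets had 3 of 27 higher and 14 lower (3 and 16 when adjusted over the list alone, adjusted p = 0.00268, and adjusted p = 0.155 with an estimated correlation). The amino acid transporter subunit SLC3A2 went against that list at 0.96. The mitochondrial folate enzyme ALDH1L2 fell (-0.67), a call lost in the fit of only the 6 libraries (adjusted p = 0.0554), on the log2(FPKM + 1) scale (adjusted p = 0.0550) and without EXT1kd adherent replicate 1 (adjusted p = 0.0578). Lysosome and autophagy genes had 15 of 31 higher and 5 lower (16 and 6 when adjusted over the list alone, adjusted p = 0.0114, and adjusted p = 0.517 with an estimated correlation), led by the protease CTSZ (1.55). Markers of carcinoma epithelium, included as another possible cell type, had 3 of 7 higher and 0 lower, also when adjusted over the list alone (adjusted p = 0.0234, and adjusted p = 0.17 with an estimated correlation), with KRT19 at 1.11 and EPCAM at 1.02.

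In all, 4633 of 17115 genes passed in adherent culture, 2609 higher and 2024 lower, of which 320 rose and 298 fell at least 2-fold. In a fit of only the 6 libraries compared the count was 3083. Of the 39 lists, 19 passed under the preset correlation, 10 up and 9 down.

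The second comparison put the same question in suspension. There the largest changes were falls. SOX11, a neural transcription factor, fell from 25.6 ± 2.8 to 3.05 ± 0.39 CPM (SD, n = 3; -3.07, SE 0.12), and the matricellular protein SPARC from 71.2 ± 3.2 to 12.5 ± 1.3 CPM (-2.51, SE 0.09). The progesterone receptor PGR (-3.19), the growth factor PDGFD (-3.11, on 19 knockdown reads, 8.82-fold lower with a 95% exact binomial interval of 5.48 to 15.02), TMEM47 (-2.92), the desmosomal protein PKP3 (-2.71), the keratin KRT19 (-2.62), the phospholipase PLA2G4A (-2.60) and SERPINB9 (-2.47) also fell. Steroid sulfatase STS was 10.3-fold lower (95% exact binomial interval 4.77 to 26.6), on 7 reads in the 3 knockdown libraries against 73 in wild type, so that its fitted log2 value of -3.31 depends on the prior count. Rises were smaller. CGA, the shared alpha subunit of glycoprotein hormones, rose from 114 ± 4.3 to 296 ± 17 CPM (SD, n = 3; 1.37, SE 0.09), followed by ZNF667 (1.26), the interferon-induced membrane protein BST2 (1.26), GADD45B (1.22), YJEFN3 (1.21), CARD9 (1.20), KCNAB3 (1.19), PNPLA7 (1.18), LIPH (1.18) and SULT1A1 (1.09).

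Genes of sterol synthesis fell in suspension knockdown cells: 0 of 25 cholesterol synthesis genes and SREBP2 targets rose and 15 fell (0 and 17 when adjusted over the list alone), with a median of -0.31. TM7SF2, a sterol reductase, was at -1.04 (SE 0.15) and HMGCS1, which makes the precursor of mevalonate, at -0.86 (SE 0.09). The call (adjusted p = 8.28e-09) was lost at adjusted p = 0.13 with an estimated correlation. Targets of p53 had 1 of 23 higher and 10 lower (2 and 14 when adjusted over the list alone, adjusted p = 0.000181, and adjusted p = 0.0529 with an estimated correlation), led by FDXR (-0.82) and the DNA repair factor DDB2 (-0.75). Ribosomal proteins had 0 of 50 higher and 15 lower (0 and 20 when adjusted over the list alone, adjusted p = 2.42e-07, and adjusted p = 0.753 with an estimated correlation). RPS3 was at -0.52, and RPL37 at -0.53 with a call lost with DESeq2 (adjusted p = 0.0670), on both FPKM scales (adjusted p = 0.0517 and 0.0508) and without WT suspension replicate 2 (adjusted p = 0.0507) or EXT1kd suspension replicate 1 (adjusted p = 0.0644). Fibroblast markers had 0 of 10 higher and 5 lower (1 and 5 when adjusted over the list alone, adjusted p = 0.0193, and adjusted p = 0.504 with an estimated correlation), with FBLN1 at -1.05.

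Heparan sulfate proteoglycan core proteins had 1 of 15 members higher and 9 lower in suspension knockdown cells (2 and 10 when adjusted over the list alone). The list's median was -0.26 (adjusted p = 0.0275, and adjusted p = 0.221 with an estimated correlation). COL18A1, whose core carries heparan sulfate, was at -0.52 and lost its call on the log2(FPKM + 0.1) scale (adjusted p = 0.0515) and without WT suspension replicate 1 (adjusted p = 0.0541) or EXT1kd suspension replicate 1 (adjusted p = 0.0543). Syndecan SDC3 was at -0.45 and lost its call on the same scale (adjusted p = 0.0575) and without WT suspension replicate 3 (adjusted p = 0.0514) or EXT1kd suspension replicate 1 (adjusted p = 0.0541). Of 19 heparan sulfate enzymes 1 rose and 3 fell (adjusted p = 0.971), among them EXT2 at -0.45 (SE 0.07), again with the shift of chromosome 11, and SULF2 at -0.31, whose call was lost without EXT1kd suspension replicate 1 (adjusted p = 0.0519). Linker and chondroitin or dermatan sulfate genes had 2 of 28 higher and 4 lower (adjusted p = 0.102), with the epimerase DSEL at -1.72 (SE 0.15) and XYLT1 at -1.06 (SE 0.19).

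The FGF and ERK feedback list did not pass in suspension (adjusted p = 0.763). Of its 19 members 1 rose, SPRED3 at 0.59, and 2 fell. FOSL1 was at -0.56 and lost its call without WT suspension replicate 1 (adjusted p = 0.0552) or 2 (adjusted p = 0.0550) and with chromosome medians removed (adjusted p = 0.142). SPRY4, ETV4, ETV5 and ETV1 were at 0.01, -0.06, 0.13 and 0.11, none past the threshold.

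In suspension 3577 genes passed, 1419 higher and 2158 lower, with 203 rises and 380 falls of at least 2-fold. Without TMM scaling the split was 1931 higher to 1783 lower, which moved the share of higher genes from 39.7% to 52.0%. The count was 2205 without WT suspension replicate 2, 2381 without WT suspension replicate 3, and 2375 with chromosome medians removed. Of the lists, 9 passed under the preset correlation and 0 with an estimated one. With chromosome medians removed, a fit chosen after seeing the data, p53 targets (adjusted p = 0.0221) and cholesterol genes (adjusted p = 0.0498) passed camera with an estimated correlation.

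The knockdown effects in the 2 cultures, which share no library, were set against each other. MID1IP1 fell in both (-2.45 adherent, -1.98 in suspension), as did FGF13 (2.66-fold and 3.99-fold lower), INPP5D (-2.46 and -1.10) and XYLT1 (-1.82 and -1.06). TMOD1, which caps actin filaments, rose in both (2.04-fold and 2.01-fold), as did RGS3 (1.95 and 0.89) and EMILIN2 (2.06 and 0.89). So did SAMD9 (1.04 and 0.84) and TSC1, a brake on mTORC1 (0.71 and 0.73). TMOD1, RGS3 and TSC1 lie on chromosome 9, whose genes shifted upward as a whole in both comparisons (medians 0.28 and 0.30). Of 1318 genes changed in both cultures, 346 rose in both and 331 fell in both, where independent lists would share 216 and 255 (Fisher's exact test across genes, p = 4.82e-21 and 1.81e-07). Another 641 went in opposite directions, where independent lists would share 497. Chromosome 9 had 285 genes higher in adherent and 295 higher in suspension knockdown cells. Chromosome 11 had 361 higher in adherent and 279 lower in suspension. The overlap counts and p-values thus also carry the chromosome shifts. Genes with many reads are called more easily in both comparisons, and genes are not independent units. Fisher's test allows for neither, so its p-values are a description only. Across 11689 genes, which are not independent replicates, the 2 effects had a Pearson's r of -0.017 and a Spearman's rho of 0.028. With chromosome medians removed, the 677 genes changed alike became 412 and the 641 changed in opposite directions became 367. Genes changed alike were 421 without WT suspension replicate 2 and 442 without WT suspension replicate 3. They were 451 without EXT1kd adherent replicate 1 and 1050 without WT adherent replicate 2.

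**Figure D4:**
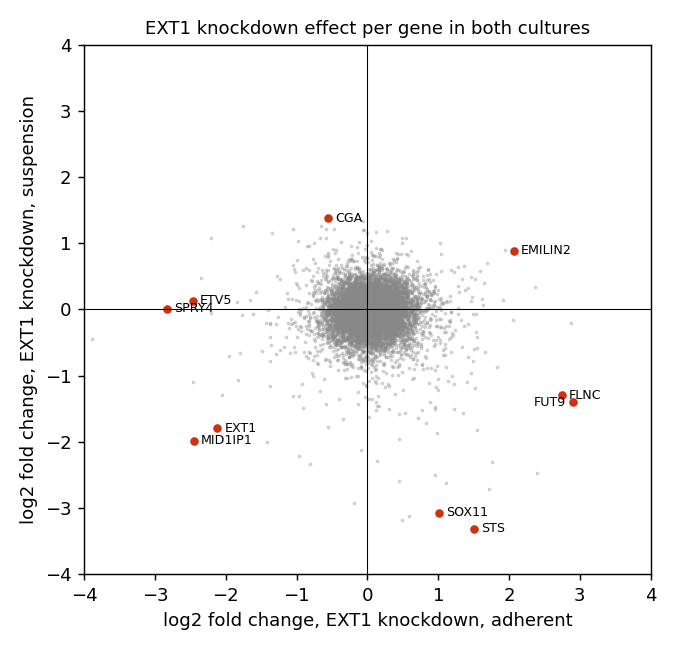
Log2 fold change of knockdown against wild type for each gene over the CPM floor, in adherent culture on the horizontal axis and in suspension on the vertical axis, with named genes in red. The cloud has no slope (r = -0.017), while EXT1 and MID1IP1 lie low on both axes, SPRY4 and ETV5 low on the adherent axis alone, and STS and SOX11 low in suspension.

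The difference between the 2 knockdown effects was tested directly. The FGF and ERK feedback list had 12 of 19 members with a higher value in suspension and 0 with a lower one (13 and 0 when adjusted over the list alone, median difference 0.64). Without removal of chromosome medians, it was the only list whose call (adjusted p = 8.63e-10) held with an estimated correlation (adjusted p = 0.0236). Its largest differences were SPRY4 (2.84, SE 0.20), ETV5 (2.60, SE 0.13), ETV4 (2.15, SE 0.13) and ETV1 (1.94, SE 0.16). SULT1A1 (3.29) and PLXNA4 (2.82) also had higher values in suspension, and so did BST2 (3.01), on 5 reads in all adherent knockdown libraries. The largest differences of the other sign were SERPINB9 (-4.86), STS (-4.82), PKP3 (-4.42), FUT9 (-4.31) and SOX11 (-4.09), each of which rose in adherent knockdown cells and fell in suspension knockdown cells.

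Matrix genes showed the difference too: 5 of 31 had a higher value in suspension and 16 a lower one (6 and 16 when adjusted over the list alone, adjusted p = 0.00282, and adjusted p = 0.28 with an estimated correlation), led by SPARC (-3.46) and COL5A1 (-2.15). YAP and TAZ targets had 0 of 24 higher and 10 lower (0 and 12 when adjusted over the list alone, adjusted p = 0.00438, and adjusted p = 0.0984 with an estimated correlation), with ARHGEF17 at -1.13 and CTGF at -1.09. Cholesterol genes had 0 of 25 higher and 11 lower, also when adjusted over the list alone (adjusted p = 6.35e-05, and adjusted p = 0.225 with an estimated correlation), with TM7SF2 at -1.19 and SC5D at -0.86. ER chaperones had 0 of 28 higher and 15 lower (1 and 17 when adjusted over the list alone, adjusted p = 0.000658, and adjusted p = 0.268 with an estimated correlation), with CRELD2 at -0.83. Integrins had 0 of 32 higher and 8 lower, also when adjusted over the list alone, with TNS3 at -1.70. Their call (adjusted p = 0.0105) was lost with an estimated correlation (adjusted p = 0.103), but passed there with chromosome medians removed (adjusted p = 0.0305). Carcinoma epithelium markers had 0 of 7 higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.0243, and adjusted p = 0.225 with an estimated correlation), with KRT19 at -3.73. In all 4114 genes passed, 1618 with a higher and 2496 with a lower value in suspension, and 17 lists passed under the preset correlation, 5 up and 12 down. With chromosome medians removed the gene count was 2610.

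Genes of whole chromosomes moved together in the knockdown comparisons. In adherent knockdown cells the median log2 fold change was 0.29 for chromosome 11, with 361 genes higher and 14 lower, 0.28 for chromosome 9, 0.26 for chromosome 3 and 0.24 for chromosome 4. In suspension it was -0.36 for chromosome 14, with 1 gene higher and 285 lower, -0.29 for chromosome 22, whose call was lost with an estimated correlation (adjusted p = 0.0505), -0.23 for chromosome 11, -0.21 for chromosome 6 and 0.30 for chromosome 9. Of 23 chromosomes 19 passed camera in adherent culture and 13 in suspension, of which 13 and 7 held with an estimated correlation. Camera compares each chromosome with all other genes, so large rises on some chromosomes can make others pass as lower. In adherent culture 11 of the calls were lower, with medians from -0.125 to -0.049, which may reflect that reference. For culture, 1 chromosome passed in wild type and 15 in knockdown cells (0 and 9 with an estimated correlation). Genes named above on chromosome 11 carry its shifts, among them TM7SF2, SC5D, DDB2, RPS3, FJX1, ARHGEF17, SLC3A2 and VPS51. The median of chromosome 11 was -0.50 for the interaction, where RPS3 was at -0.62. With chromosome medians removed, 54.3% of the adherent and 54.8% of the suspension knockdown calls were kept in direction, and 85.1% and 84.6% of those of at least 2-fold.

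**Figure D5:**
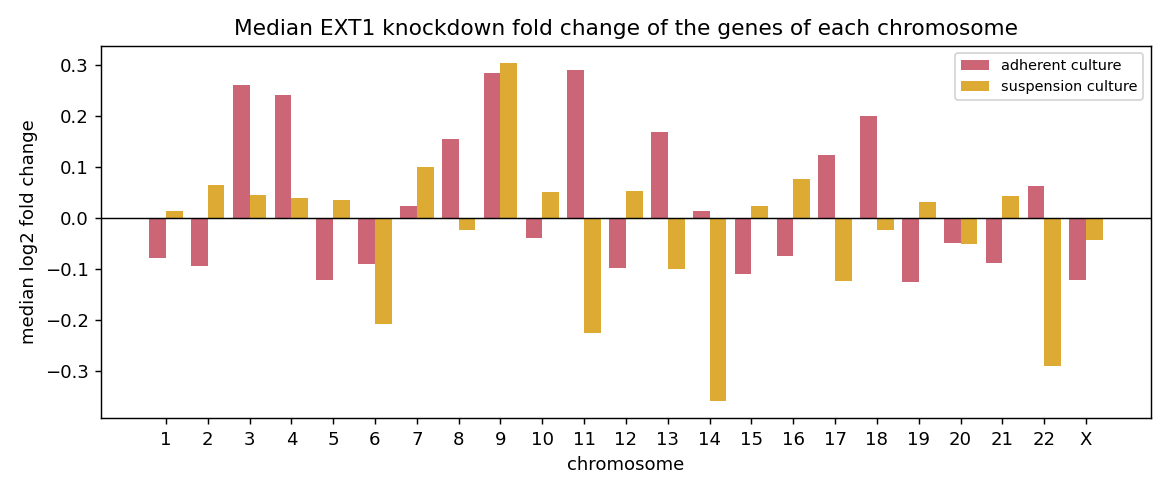
Median log2 fold change of knockdown against wild type over the genes of each chromosome with a mean CPM of at least 5, with bars for adherent and suspension culture. Chromosome 9 is high in both cultures (0.28 and 0.30), chromosome 11 is high in adherent (0.29) and low in suspension cells (-0.23), and chromosome 14 is low in suspension (-0.36).

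The third comparison set suspension against adherent culture in wild-type cells. Most targets of bone morphogenetic protein (BMP) and TGF-beta signalling on the list fell in suspension. ID3, an inhibitor of helix-loop-helix transcription factors, fell from 109 ± 29 to 3.94 ± 0.73 CPM (SD, n = 3; -4.78, SE 0.18), ID1 by 4.45 (SE 0.16) and ID2 by 2.94 (SE 0.10), while the inhibitory SMAD6 was 13.9-fold lower. Of 16 BMP and TGF-beta targets 4 rose and 10 fell (4 and 11 when adjusted over the list alone), with a median of -1.22 (adjusted p = 0.0013, and adjusted p = 0.0473 with an estimated correlation). Other large falls were XYLT1 (-2.61), DOK3 (-2.31), SAMD11 (-2.29), carbonic anhydrase CA2 (-2.23), PRR22 (-2.21) and HOXB6 (-2.09). The largest rise was BST2, 51.1-fold higher (95% exact binomial interval 32.9 to 84.0, from 20 reads to 919), followed by EPS8L2 (4.60), INPP5D (21.1-fold), TSPAN11 (4.36), CGA (4.20), MAP6 (4.09), the serine protease HTRA1 (4.05), THBS4 (3.99, 15.9-fold with an interval of 11.9 to 21.7), LUM (3.96) and VSTM2B (3.95).

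Cholesterol synthesis, p53 targets and matrix genes rose in wild-type suspension cells. Of 25 cholesterol genes 22 rose and 1 fell (23 and 1 when adjusted over the list alone, median 1.02, adjusted p = 4.02e-13, and adjusted p = 0.0265 with an estimated correlation). HMGCS1 rose from 176 to 780 CPM (2.15, SE 0.09) and INSIG1, which retains SREBP in the ER, by 1.93 (SE 0.06). Of 23 p53 targets 21 rose and 0 fell, also when adjusted over the list alone (median 0.84, adjusted p = 5.54e-11, and adjusted p = 0.0022 with an estimated correlation), with the cyclin-dependent kinase inhibitor CDKN1A at 2.11 (SE 0.10) and FDXR at 1.68 (SE 0.13). Of 31 matrix genes 25 rose and 1 fell, also when adjusted over the list alone (median 0.94, adjusted p = 5.19e-10, and adjusted p = 0.0423 with an estimated correlation), with SPARC at 2.48 and LOXL1 at 2.35. Heparan sulfate proteoglycan core proteins had 12 of 15 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.000186, and adjusted p = 0.0265 with an estimated correlation), with SDC3 at 1.82 and SDC1 at 1.58. The sulfatase SULF1 rose by 3.47 (SE 0.19), while the heparan sulfate enzyme list did not pass, with 6 of 19 higher and 3 lower (adjusted p = 0.612).

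Interferon response genes had 17 of 30 higher and 1 lower in wild-type suspension cells, also when adjusted over the list alone (adjusted p = 0.000141, and adjusted p = 0.0265 with an estimated correlation), led by BST2 and OAS3 (3.42). Integrins had 20 of 32 higher and 4 lower, also when adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.0265 with an estimated correlation), with ITGA3 at 1.38 and ITGA8 at -1.71. Neural genes known in HEK293 had 12 of 19 higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.00429, and adjusted p = 0.044 with an estimated correlation), with MAP2 at 2.32 and NES at 1.80. Proteasome genes had 1 of 33 higher and 23 lower, also when adjusted over the list alone (adjusted p = 0.000118, and adjusted p = 0.46 with an estimated correlation), with PSMD2 at -0.74. Fatty acid synthesis genes had 11 of 17 higher and 3 lower (12 and 3 when adjusted over the list alone, adjusted p = 0.0014, and adjusted p = 0.111 with an estimated correlation), with FADS2 at 1.79. Heat shock genes had 2 of 18 higher and 12 lower (2 and 13 when adjusted over the list alone, adjusted p = 0.00284, and adjusted p = 0.46 with an estimated correlation), with the small chaperone HSPB1 against the list at 1.58. Carcinoma epithelium markers had 6 of 7 higher and 0 lower, also when adjusted over the list alone (adjusted p = 0.00655, and adjusted p = 0.0585 with an estimated correlation), with CDH1 at 1.73. In all 9534 genes passed, 4735 higher and 4799 lower, with 1799 rises and 653 falls of at least 2-fold. Without TMM scaling the split was 5217 higher to 4156 lower. Of the lists 17 passed, of which 8 held with an estimated correlation.

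The fourth comparison set the cultures against each other in knockdown cells. Most BMP and TGF-beta targets fell here too, with ID1 at -4.77 (SE 0.17), ID3 at -4.76 (SE 0.18) and SMAD6 at -3.97 (SE 0.12), and 2 of 16 list members higher and 11 lower, also when adjusted over the list alone (adjusted p = 0.00016, and adjusted p = 0.0667 with an estimated correlation). Targets of p53 had 19 of 23 higher and 0 lower, also when adjusted over the list alone (median 0.69), with CDKN1A at 2.29 and the death receptor FAS at 1.65. Theirs was the only list call of this comparison (adjusted p = 7.39e-08) to hold with an estimated correlation (adjusted p = 0.00635). FGF and ERK feedback targets had 15 of 19 higher and 3 lower, also when adjusted over the list alone (median 1.27, adjusted p = 4.92e-06, and adjusted p = 0.0637 with an estimated correlation), with ETV4 at 4.20, SPRY4 at 4.02 and ETV5 at 3.18. Cholesterol genes had 19 of 25 higher and 2 lower, also when adjusted over the list alone (adjusted p = 1.14e-07, and adjusted p = 0.0699 with an estimated correlation), with IDI1 at 1.63 and MVD at 1.53.

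BST2 had 5 reads in the adherent knockdown libraries and 2182 in suspension, a 433-fold rise (95% exact binomial interval 185 to 1333). CGA rose by 6.13 (SE 0.12), INPP5D was 55.3-fold higher (interval 34.8 to 93.7), and VSTM2B (43.6-fold, interval 30.9 to 63.6), PLXNA4 (29.4-fold, interval 19.2 to 47.2), RINL (4.78), SULT1A1 (4.66), LSAMP (23.2-fold, interval 16.8 to 33.0) and NTNG2 (4.38) followed. STS was 119-fold lower (interval 57.5 to 297), PDGFD 37.2-fold lower (interval 23.6 to 62.1), and PUDP (-4.69), SOX11 (-4.67), SERPINB9 (-4.01), KRT19 (-3.89) and TMEM47 (-3.76) fell as well. ER chaperones had 3 of 28 higher and 20 lower (3 and 21 when adjusted over the list alone, adjusted p = 0.000114, and adjusted p = 0.222 with an estimated correlation), with DNAJB11 at -1.09 and MANF at -0.88. YAP and TAZ targets had 4 of 24 higher and 15 lower, also when adjusted over the list alone (adjusted p = 0.0194, adjusted p = 0.0974 with an estimated correlation and adjusted p = 0.0586 with chromosome medians removed, where the list median went from -0.37 to -0.23), with DLC1 at -1.21 and MYOF against the list at 1.90. Matrix genes had 18 of 31 higher and 7 lower, also when adjusted over the list alone (adjusted p = 0.00794, and adjusted p = 0.347 with an estimated correlation), with TNC at 2.71 and FBN1 at 2.54. Proteoglycan core proteins had 10 of 15 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.00593, and adjusted p = 0.0699 with an estimated correlation), with SDC3 at 1.69. Neural genes had 13 of 19 higher and 4 lower, also when adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.0699 with an estimated correlation), with MAP2 at 2.54. SULF1 rose by 3.38 (SE 0.20). In all 9534 genes passed, as many as in wild type, 4579 higher and 4955 lower. Without TMM scaling the split was 5227 higher to 4241 lower. Rises of at least 2-fold were 1687 and falls 770, and 13 lists passed.

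The culture effects of the 2 lines, which share no library, were correlated. Of 6549 genes changed in both lines, 3015 rose in both and 3095 fell in both, where independent lists would share 1267 and 1389, and 439 went in opposite directions. Pearson's r across 11689 genes was 0.732 and Spearman's rho 0.695. BST2, INPP5D, CGA, VSTM2B and NECTIN4 (3.87 in wild type, 3.67 in knockdown cells) led the shared rises. ID3, ID1, SMAD6, SAMD11 (-2.29 and -2.88) and CA2 (-2.23 and -2.69) led the shared falls.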

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

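Of the tests in this part, 5 were chosen only after the result was seen: the sign of windows within chromosomes with its shuffle, the FGF list in suspension, the summed FGF receptor transcripts, the removal of chromosome medians from the correlation between cultures, and the comparison of culture effects between the lines.

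The results here are those whose knockdown effect differed between adherent and suspension culture by a test of the difference. They comprise 4114 genes, 17 gene lists and 20 chromosomes. Among 50 drawn splits of the 12 libraries into 4 groups of 3, only the real one, 1 of 50, reached as many genes. The highest other split gave 3269, which points to a structure of the samples whose cause was not tested. For lists the real 17 was met by another split at 17, and for chromosomes the real 20 by another at 20, each 2 of 50. Chance cannot be excluded from these counts. The other splits mix cultures and lines within groups, so they carry those effects and a wider spread rather than chance alone, a judgement made after the counts were seen.

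Among the genes named, values given as the suspension effect minus the adherent effect were highest for SULT1A1 (3.29), BST2 (3.01), SPRY4 (2.84), PLXNA4 (2.82), ETV5 (2.60), GADD45B (2.27) and ETV4 (2.15). They were also above 0 for ETV1 (1.94), CGA (1.93), ZNF667 (1.92), LSAMP (1.80), YJEFN3 (1.69), VSTM2B (1.49), DOK3 (1.40), INPP5D (1.36), KCNAB3 (1.26), CDH11 (1.26), CARD9 (1.25), SPRED3 (1.18), RINL (1.17) and LIPH (1.05). Smaller positive differences were those of NTNG2 (0.99), FBN1 (0.96), ID2 (0.91), PNPLA7 (0.91), HOXB6 (0.84), XYLT1 (0.76), RPS23 (0.65), SULF2 (0.50), MID1IP1 (0.47) and TNC (0.40). The most negative were SERPINB9 (-4.86), STS (-4.82), PKP3 (-4.42), FUT9 (-4.31), SOX11 (-4.09), PUDP (-4.07), FLNC (-4.05), KRT19 (-3.73), PDGFD (-3.69), PGR (-3.67), SPARC (-3.46), CTSZ (-3.37), CSRP1 (-3.09) and PLA2G4A (-3.04). They were followed by TMEM47 (-2.73), RIN3 (-2.69), DSEL (-2.54), FRRS1L (-2.21), COL5A1 (-2.15), EPS8L2 (-2.05) and LUM (-2.02), and by HTRA1 (-1.87), PARP14 (-1.78), TNS3 (-1.70), FBLN1 (-1.68), THBS4 (-1.62), LAMA1 (-1.59), LOXL2 (-1.59), FADS2 (-1.50), OAS3 (-1.48), MAP6 (-1.34), VPS51 (-1.33), EPCAM (-1.28), TM7SF2 (-1.19), EMILIN2 (-1.17), ARHGEF17 (-1.13), TSPAN11 (-1.11), CTGF (-1.09) and RGS3 (-1.06). Smaller negative differences were those of SLC3A2 (-0.98), EXT2 (-0.96), NES (-0.88), SC5D (-0.86), ITGA3 (-0.86), CRELD2 (-0.83), DDB2 (-0.78), HMGCS1 (-0.77), FJX1 (-0.69), HPSE (-0.68), MANF (-0.62), RPS3 (-0.62), EXTL3 (-0.62), SAMD11 (-0.59), FGF13 (-0.58), ITGA8 (-0.57), INSIG1 (-0.48) and DNAJB11 (-0.38).

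Whole chromosomes shifted in the knockdown comparisons, with medians between -0.36 and 0.30. A correction for GC content and gene length left the medians at a median ratio of 0.977 to their size before it, over the 99.8% of genes with a GC value, which argues against such a bias. No single library set the shifts, since leaving out any of them left at least 0.754 of each, the lowest being chromosome 18 in adherent culture and barely past the bound of 0.75 set in advance. In 10 pairs of chromosome and comparison with an absolute median of at least 0.2, all 125 windows of 10 Mb (100%) had the sign of their chromosome. Genes shuffled along these chromosomes gave a mean of 99.98% over 100 shuffles, so the choice of the chromosomes fixed the outcome. The sign of these windows thus decides nothing. Outside these pairs, chromosome 5 had a suspension median of 0.035 that hid a step, looked up after the results were seen. Its windows up to position 50000000 lay at -0.257 to -0.198 and those beyond at 0.035 to 0.118. Such a step was not confined to chromosome 5. On chromosome 8 the window from 140000001 to 150000000 lay at -0.175 in adherent and -0.242 in suspension culture. The other windows of chromosome 8 lay at 0.093 to 0.264 and at -0.115 to 0.094. The causes of these steps were not tested. Copy number differences between the cell populations, as could arise while HEK293 sublines are passaged, stay a hypothesis without DNA data, and a regulatory cause acting along whole chromosomes was not tested.

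The fall of FGF and ERK feedback targets was seen in adherent knockdown cells alone of the 2 knockdown comparisons. By the interaction test the 2 knockdown effects differed. That test cannot tell culture from other differences between the 2 knockdown populations. Between the cultures 15 chromosomes passed camera in knockdown cells and 1 in wild type (9 and 0 with an estimated correlation). With chromosome medians subtracted the list's median was still -0.465, which argues against chromosome shifts as its source. Loss of EXT1 whatever the culture is argued against by the list median of 0.0552 in suspension, where EXT1 fell almost as far. Fewer FGF receptor transcripts in sum are argued against by the summed FGFR1 to FGFR4 level in adherent cells. It went from 221.6 ± 15.7 to 245.4 ± 6.65 CPM (SD, n = 3), a change of 10.7%. The sum cannot show whether a less abundant receptor fell. A loss of heparan sulfate as FGF co-receptor may account for the pattern. It would have to matter only with serum, attachment or the growth factors of that medium. This was not tested. Medium, attachment and harvest differ together, and the 2 knockdown populations may differ for other reasons.

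Knockdown effects did not correlate between the cultures over all genes. More genes than independent lists would share changed alike (677 against 472), and more changed in opposite directions (641 against 497). With chromosome medians removed these counts were 412 and 367. The expected counts do not allow for genes with many reads, which are called more easily in both comparisons. Subtracting chromosome medians left Pearson's r at -0.0115, which argues against chromosome shifts of opposite sign as the reason. Noise between libraries is argued against by the correlation of effects from disjoint libraries within a culture, 0.696 in adherent and 0.809 in suspension cells. Variation between separately grown cells is not covered, since the libraries of a group may not come from separate cultures. Exchanged culture labels in 1 line are argued against by the r of 0.732 between the culture effects of the lines. Whether the 2 knockdown populations were the same cells adapted to each culture, or separate populations that could differ for other reasons, stays open.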

How the results depend on the processing

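Chromosome medians removed was the only alternative chosen after seeing the data. The 189 results for named genes gave 4324 values under the alternatives, of which 4293 kept their direction and side of the threshold, 28 fell short of it, 3 passed it and 0 reversed. Those that fell short are named with their genes in the results. Depth limits BST2, STS, INPP5D, PDGFD, PLXNA4, VSTM2B, LSAMP and THBS4, with under 10 reads in a library of a comparison. Their folds between 2 groups carry intervals there, but their interaction values carry none.

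Fitting only the 6 libraries compared gave 3083 genes in the adherent knockdown comparison, where fewer samples estimate the spread. With an estimated correlation, lists past the threshold were 1 for adherent knockdown, 0 for suspension knockdown, 8 for culture in wild type, 1 for culture in knockdown cells and 1 for the interaction, and chromosomes were 7 for suspension knockdown, 0 for culture in wild type, 9 for culture in knockdown cells and 9 for the interaction. Fry, which does not compare a list with other genes, gave 19, 26 and 30 lists for suspension knockdown, culture in wild type and culture in knockdown cells. The stricter filter gave 5 chromosomes for culture in wild type, and the cause was not tested.

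With chromosome medians removed, genes were 2375 for suspension knockdown, 2610 for the interaction and 412 for knockdown in both cultures. Chromosomes were 0 in all 5 comparisons, by construction. With an estimated correlation as well, p53 targets and cholesterol genes passed camera in suspension knockdown and integrins in the interaction. For culture in wild type, the proteoglycan core, matrix, BMP and TGF-beta, interferon and neural lists then fell short (adjusted p from 0.0600 to 0.0664).

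Leaving out 1 library at a time gave 3177 to 5098 genes for adherent knockdown, 2205 to 4692 for suspension knockdown, 8410 to 9580 and 8368 to 10170 for culture in wild type and knockdown cells, 3164 to 5072 for the interaction, 421 to 1050 for knockdown in both cultures and 5462 to 6452 for culture in both lines. EXT1 ranged from -2.15 to -2.11 in adherent culture and from -1.84 to -1.72 in suspension. Lists ranged over 14 to 20, 6 to 12, 14 to 17, 12 to 13 and 13 to 18 for the 5 comparisons in the same order, and chromosomes over 18 to 20, 11 to 14, 1 to 3, 14 to 17 and 19 to 20. The 2205 and 421 were without WT suspension replicate 2, the 1050 and the 3 chromosomes for culture in wild type without WT adherent replicate 2, and without WT adherent replicate 3 that count was 2. The cause was not tested.

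With the replicate number as a replicate block, counts were 4490, 3441, 9480, 9463 and 4019 for the 5 comparisons, each within 1.5 times the count without it. The numbers do not pair the samples: correlations between deviations of same-numbered libraries ran from -0.155 to 0.146, with 1 of 18 above 0.1, and 0 libraries correlated best with their own number in all other groups.

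Splits of the 6 libraries of each comparison number 10 with the real one included, too few for a share under 0.05. Each other split also mixes the 2 groups compared, which widens the spread within groups. Its count of 0 genes was thus largely set in advance. Real and highest other values were 4633 and 0 genes, 19 and 9 lists and 19 and 13 chromosomes for adherent knockdown, 3577 and 0 genes, 9 and 13 lists (4 of 10 splits as large) and 13 and 10 chromosomes for suspension knockdown, 9534 and 0 genes, 17 and 14 lists and 1 and 4 chromosomes (7 of 10) for culture in wild type, and 9534 and 0 genes, 13 and 12 lists and 15 and 10 chromosomes for culture in knockdown cells. Of 50 drawn splits of all libraries, 1 reached the 677 genes shared by the knockdown comparisons and 1 the 6110 shared by the culture comparisons, the real one each time, with 0 the highest other. Those splits mix cultures and lines within groups, so chance cannot be excluded from these counts.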

Other observations

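Both tests in this part, of HOX genes and of a region on the X chromosome, were chosen only after the result was seen.

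Lists not described above added shifts in adherent knockdown cells, all lost with an estimated correlation. Genes of mitosis (2 of 30 higher, 10 lower, adjusted p = 0.00873), oxidative phosphorylation (3 of 43 higher, 15 lower, adjusted p = 0.00927), glycolysis (0 of 23 higher, 7 lower, adjusted p = 0.00927), the proteasome (2 of 33 higher, 11 lower, adjusted p = 0.0114), DNA replication (2 of 35 higher, 10 lower, adjusted p = 0.0257) and mitochondrially encoded proteins (0 of 13 higher, 4 lower, adjusted p = 0.0267) were lower. ER chaperones (11 of 28 higher, 1 lower, adjusted p = 0.0114), clustered protocadherins (3 of 7 higher, 0 lower, adjusted p = 0.0265), N-glycosylation (14 of 40 higher, 3 lower, adjusted p = 0.0284) and cadherins (11 of 28 higher, 3 lower, adjusted p = 0.0344) were higher. Their adjusted p-values with an estimated correlation lay between 0.17 and 0.521. With chromosome medians removed 4 of these calls were lost as well. The medians shrank for glycolysis (from -0.115 to -0.067, adjusted p = 0.0647), N-glycosylation (from 0.098 to 0.038, adjusted p = 0.106) and cadherins (from 0.171 to 0.115, adjusted p = 0.0661), and little for ER chaperones (from 0.118 to 0.097, adjusted p = 0.0796). In suspension knockdown cells mitosis (0 of 30 higher, 9 lower, adjusted p = 0.0065), fatty acid synthesis (0 of 17 higher, 6 lower, adjusted p = 0.0193), ER chaperones (1 of 28 higher, 10 lower, adjusted p = 0.0427) and Wnt targets (0 of 17 higher, 5 lower, adjusted p = 0.0427) were lower, with adjusted p between 0.421 and 0.753 with an estimated correlation. Removing chromosome medians ended the call of fatty acid synthesis (median from -0.179 to -0.087, adjusted p = 0.0909). It also ended that of Wnt targets, whose median stayed as large (from -0.196 to -0.213, adjusted p = 0.0599). Shifts of whole chromosomes thus do not account for that median, while shifts of parts of chromosomes were not removed.

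In wild-type suspension cells DNA replication genes were lower (3 of 35 higher, 18 lower, adjusted p = 0.00602, and adjusted p = 0.364 with an estimated correlation), as were replication-dependent histones (1 of 18 higher, 10 lower, adjusted p = 0.0419, and adjusted p = 0.551 with an estimated correlation), whose transcripts lack poly-A tails, so that poly-A selection catches them poorly. Ribosomal proteins (18 of 50 higher, 1 lower, adjusted p = 0.0118, and adjusted p = 0.808 with an estimated correlation), fibroblast markers (6 of 10 higher, 1 lower, adjusted p = 0.0182, and adjusted p = 0.364 with an estimated correlation) and SRF targets (10 of 21 higher, 4 lower, adjusted p = 0.0407, and adjusted p = 0.357 with an estimated correlation) were higher. In knockdown cells interferon response genes (17 of 30 higher, 6 lower, adjusted p = 0.0113, and adjusted p = 0.121 with an estimated correlation) and ribosomal proteins (18 of 50 higher, 3 lower, adjusted p = 0.0193, and adjusted p = 0.757 with an estimated correlation) were higher in suspension, and N-glycosylation (6 of 40 higher, 20 lower, adjusted p = 0.0111, and adjusted p = 0.281 with an estimated correlation) and proteasome genes (5 of 33 higher, 17 lower, adjusted p = 0.0201, adjusted p = 0.658 with an estimated correlation and adjusted p = 0.325 with chromosome medians removed, which took the median from -0.245 to -0.102) lower. The lists for COPII and COPI coats, ER shape, linker synthesis, NRF2, heparan sulfate enzymes, hypoxia, metallothioneins and renal epithelium, 8 in all, passed in no comparison.

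Another 10 lists differed between the cultures in their knockdown effect, all lost with an estimated correlation. Values higher in suspension prevailed for ATF4 targets (10 of 27 higher, 3 lower, adjusted p = 0.0103), glycolysis (6 of 23 higher, 1 lower, adjusted p = 0.0154), DNA replication (8 of 35 higher, 3 lower, adjusted p = 0.0172) and heat shock genes (4 of 18 higher, 0 lower, adjusted p = 0.0363). Lower values prevailed for fibroblast markers (0 of 10 higher, 6 lower, adjusted p = 0.00582), N-glycosylation (3 of 40 higher, 14 lower, adjusted p = 0.0164), fatty acid synthesis (1 of 17 higher, 7 lower, adjusted p = 0.0281), cadherins (2 of 28 higher, 12 lower, adjusted p = 0.0363), AAV attachment and entry factors (2 of 30 higher, 7 lower, adjusted p = 0.0395) and clustered protocadherins (0 of 7 higher, 3 lower, adjusted p = 0.0487). Their adjusted p-values with an estimated correlation lay between 0.232 and 0.497. With chromosome medians removed 5 of these calls were lost too. The medians shrank for N-glycosylation (from -0.17 to -0.094, adjusted p = 0.0666), fatty acid synthesis (from -0.186 to -0.097, adjusted p = 0.105), cadherins (from -0.213 to -0.087, adjusted p = 0.0534) and AAV factors (from -0.176 to -0.119, adjusted p = 0.0534), and little for glycolysis (from 0.135 to 0.124, adjusted p = 0.105).

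HOXB6 among the largest falls in suspension led to a test of all HOX genes. Of 35 measured, 2 were higher and 27 lower in wild-type suspension cells (median -0.996), and 1 higher and 21 lower in knockdown cells (median -0.75). The larger camera p of the 2 lines was 8.08e-07, or 0.00973 with an estimated correlation. HOX genes may thus be lower as a family in suspension, a hypothesis found and tested on the same data.

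STS and its neighbour PUDP on the X chromosome were lower in suspension knockdown cells and higher in adherent knockdown cells (1.51 and 1.76, values looked up after this was seen). A local loss of DNA could lower both in suspension, and the median of the measured genes within 2 Mb of STS was -2.31. That test is void, since only 3 genes were measured there and 2 of them are the pair that prompted it. The verdict was set to open after its value was seen, for that reason. The remaining gene, ANOS1, chosen after its value was seen, was at 0.28 (adjusted p = 0.0243), so any loss would have to end before it.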
